A study of Mus musculus with 6 samples.

How the data were processed

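ILC3s of wild-type mouse small intestine were sorted by the gate CD45 positive, lineage negative, CD90.2 high, CD127 positive and KLRG1 negative, per the series' design text, and cultured with IFN-γ, with or without IGF-1. Libraries were made from lysed cells with the SMART-Seq HT kit, per the labels' protocols. The kit makes full-length cDNA and does not mark strand. The sample labels name the groups only as control and IGF-1, and that the control cultures also held IFN-γ is from the design text. The 6 libraries were grouped by their titles, 3 per group.

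The deposited values are raw counts per gene. Per the submitters' processing notes, the tools were fastp 0.23.2, HISAT2 2.2.1, SAMtools 1.15.1 and featureCounts 1.5.3 with the genome build GRCm39. The notes as used here give no role for each tool, and the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies therefore cannot be told apart with certainty. The table holds 33157 rows, of which 9897 had no count in any library, and 88 rows repeat a symbol that an earlier row has and were kept as rows of their own. Mitochondrial genes appear under RefSeq names such as COX1. Every column of values was used, and no row lacked a gene name. Gene positions are not given because the reference in use was of another build.

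Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 13483 genes and removed 0.0806% of the counts. Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, estimateDisp, glmQLFit and glmQLFTest with default settings, group as the only term, and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Gene lists (22 of biology and 12 of markers of other cell types, RNA quality and handling) were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the biology lists and over the marker lists separately, with camera's estimated correlation and fry beside it. Lists with fewer than 3 tested members were not tested. By fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes, 2 biology lists were higher (sterol and fatty acid synthesis, ATF4 and amino acids) and 3 lower (IFN-γ response, MHC class I, ILC3 identity) at an adjusted p under 0.05.

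The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest log2 fold changes per direction among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between groups, leaving out predicted gene models. It added up to 3 members with the smallest p from each biology list, the most abundant and up to 2 further members from each marker list, and a fixed set of receptors, IFN-γ targets, ILC3 factors and cytokines. Other members of the lists, and genes in the closing observations, were named after their values were seen. The values of some genes that the rule names are not reported here.

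The 3 libraries of each group differ from one another by far more than sampling noise, with a chi-square per degree of freedom of 41.5 to 97.6 for each pair, so none was a duplicate. Log2 CPM correlated across genes at 0.947 to 0.958 within groups and 0.941 to 0.954 between them. Counts from PCR reads without molecular identifiers are not independent molecules, and no interval for counting error is given. With 3 libraries against 3 an exact two-sided permutation test of a single gene cannot go below p = 0.1.

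The test was checked on 5 simulated datasets of the comparison with IGF-1, drawn from the means, dispersions and library sizes of the 13483 genes, each with 200 changed genes. It called 26.8% of genes changed by 0.6 on the log2 scale, 78.0% at 1, 97.2% at 1.5 and 99.6% at 2, and on average 12.2 of the 12833 unchanged genes that passed the filter again in the simulated counts. A planted list of 30 genes at -0.4 had a camera p under 0.05 in 5 of the 5 datasets and an unchanged list in 0. The changed genes and the list genes were drawn from those with a mean of at least 10 CPM. Each gene was simulated independently of the others. The check therefore could not show how camera with the preset correlation behaves for lists of correlated genes. Among the biology lists the highest estimated correlation was 0.49, for NF-kB targets.

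Alternatives were a fit with the replicate number as a block, RLE, upper quartile and library size scaling, DESeq2 1.42.0 with and without the block, limma-voom with and without sample quality weights, no filter and a stricter filter (10 CPM in 3 libraries), each library left out, adjusted p of 0.1 and 0.01, and for lists an estimated correlation and only members of at least 10 CPM. A robust dispersion fit and a per-library offset for transcript length and GC content were added after the data had been examined. Length and GC content came from GENCODE M21 transcripts and were found for 97.2% of the genes tested.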

Results

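RNA was sequenced from group 3 innate lymphoid cells (ILC3s), tissue-resident lymphocytes of the gut, sorted from wild-type mouse small intestine. All cells were cultured for 4 h with interferon-γ (IFN-γ) at 20 ng/mL, a cytokine of type 1 immunity. In 1 of the 2 groups insulin-like growth factor 1 (IGF-1) was added at 200 ng/mL. Each group held 3 libraries, and total counts ranged from 32573713 to 39206449 per library. There were no cultures without IFN-γ, so each difference below is between cultures with and without IGF-1 that were all exposed to IFN-γ. The labels do not say whether the 3 libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical. Gene values are TMM-normalised CPM (read counts scaled to a common library size), given as mean ± SD with n = 3 per group. Fold changes are log2 values of IFN-γ plus IGF-1 over IFN-γ alone with the standard error (SE), and adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test.

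The comparison asked how IGF-1 changes the transcriptome of ILC3s responding to IFN-γ. With IGF-1, guanylate-binding protein Gbp2, the checkpoint ligand Cd274 and the kinases Pim1 and Pim2 were lower. The activating receptor Ncr1, the ERK phosphatase Dusp6, the sterol enzyme Idi1 and the cytokine Csf2 (GM-CSF) were higher. Gbp2 fell from 1559 ± 106 to 623 ± 19.0 CPM (log2 fold change -1.32, SE 0.11, adjusted p = 0.00180). Ncr1 rose from 28.2 ± 1.09 to 71.5 ± 6.62 CPM (log2 fold change 1.34, SE 0.14, adjusted p = 0.00903). Of 13483 genes tested, 31 were higher and 36 lower at an adjusted p under 0.05. In all 67 of them the 3 libraries of one group lay entirely on one side of the other group. Among all genes tested 18.0% had groups that did not overlap, against 10% by chance for 3 libraries against 3, and 1593 had an unadjusted p under 0.05 where 674 are expected by chance. Without control replicate 1, 24 genes were higher and 31 lower, but only 15 and 17 of these were among the 67. The gene counts depended more on each of the other libraries. They were 3 higher and 3 lower without control replicate 2, 0 and 2 without control replicate 3, 0 and 0 without IGF-1 replicate 1, 0 and 1 without IGF-1 replicate 2, and 6 and 11 without IGF-1 replicate 3. All 67 genes kept their direction and an unadjusted p under 0.05 in each of these fits, but many lost their call. The 67 were picked from these same libraries by small p-values, and their groups did not overlap. Their kept direction and unadjusted p were therefore largely set by that choice. Over the 6 fits that each leave out 1 library, the call was lost in 1 for Gbp2 (without IGF-1 replicate 1, adjusted p = 0.0692), 3 for Ncr1 and for Pim2, 4 for Pim1, 5 for Cd274, Dusp6 and Idi1, and all 6 for Csf2 (adjusted p from 0.0651 to 0.209).

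**Figure D1:**
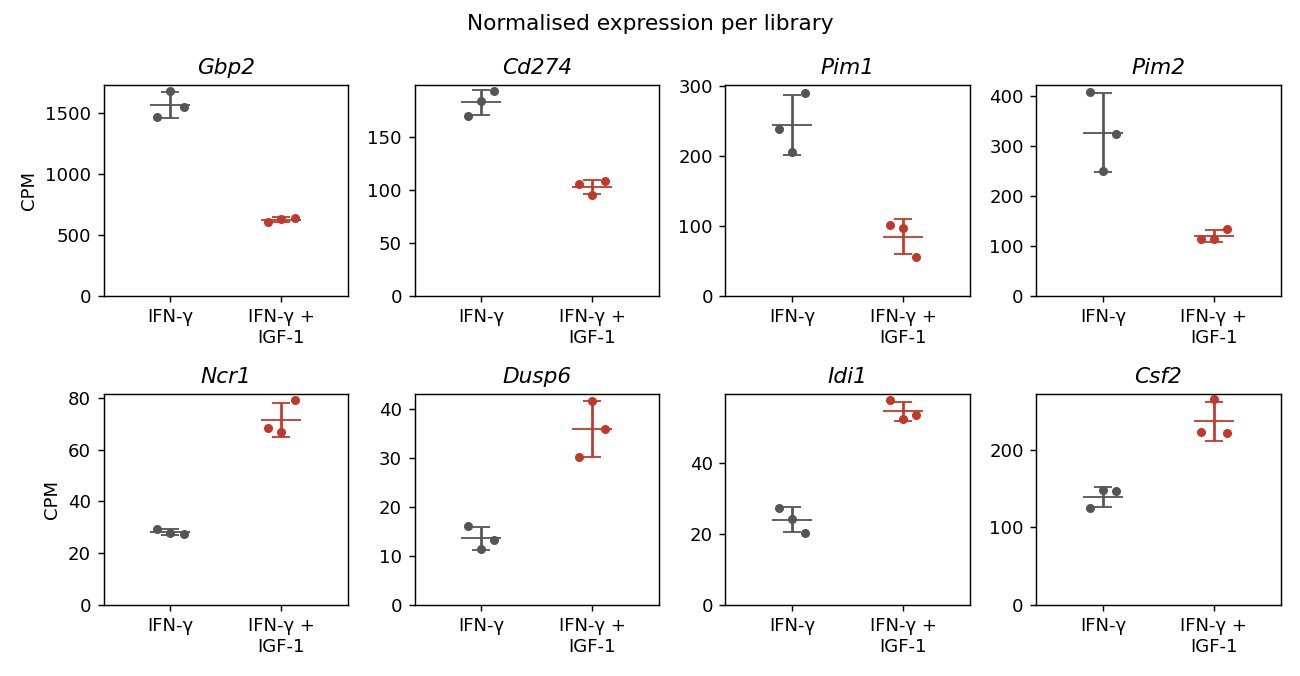
CPM of 8 genes in each library of the 2 groups (points), with the group mean and SD (bars). For every gene drawn, the 3 libraries with IGF-1 lie entirely above or entirely below the 3 with IFN-γ alone.

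At a mean of at least 10 CPM and with predicted gene models left out, the genes with the largest decreases were Pim1 (244 ± 42.7 to 84.6 ± 25.2 CPM, log2 fold change -1.53, SE 0.22, adjusted p = 0.0222), Slc25a27 (-1.47, SE 0.26), Pim2 (327 ± 78.6 to 120 ± 12.1 CPM, -1.44, SE 0.18), Gbp11 (-1.44, SE 0.21) and the transcriptional repressor Bach2 (-1.43, SE 0.25). Cpne7, Gbp2, Tnfrsf26, the phosphodiesterase Pde5a and the adhesion molecule Epcam followed, with log2 fold changes from -1.34 to -1.13. The genes with the largest increases at a mean of at least 10 CPM were Susd2 (4.13 ± 1.77 to 21.0 ± 5.57 CPM, log2 fold change 2.35, SE 0.35, adjusted p = 0.0227) and Ppp1r14c (1.52, SE 0.27). Nkg7, a granule membrane protein of cytotoxic lymphocytes, rose from 31.2 ± 3.36 to 89.3 ± 24.8 CPM (log2 fold change 1.51, SE 0.21, adjusted p = 0.0201). Galectin-1 (Lgals1) rose from 265 ± 52.8 to 741 ± 238 CPM, by 1.48 (SE 0.24) on the log2 scale. The receptors Cd160 (1.48, SE 0.20) and Cd244a (1.25, SE 0.16), Dusp6 (1.40, SE 0.20), guanine deaminase Gda (1.36, SE 0.16), Ncr1 and the transporter Slc16a6 (1.21, SE 0.19) completed the 10.

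Genes of the IFN-γ response were lower with IGF-1. Of 33 measured members, 30 had a negative log2 fold change, and the median was -0.42 on the log2 scale, a change of -25.1%. Gbp2, Cd274 (182 ± 11.6 to 103 ± 6.61 CPM, log2 fold change -0.82, SE 0.12, adjusted p = 0.0222) and Serpina3g (1432 ± 141 to 896 ± 38.7 CPM, -0.68, SE 0.11, adjusted p = 0.0392) passed the test over all genes. When adjusted over the list alone, 16 members were lower and 0 higher, the lower ones including Gbp3, Gbp4, Ifi47, Socs1, Wars1, Irf1 and Cxcl10. The list was called by camera with a preset correlation (adjusted p = 3.30e-18), and it was the single list that held with an estimated correlation (adjusted p = 0.0106). With the preset correlation, every other way to split the 6 libraries into 3 and 3 also gave called lists, from 1 to 8 against 11. Those splits mix the groups unevenly, so part of any real difference stays in them. The transcription factor Irf1 (749 ± 17.7 and 561 ± 30.7 CPM, -0.42, SE 0.11, adjusted p = 0.142) did not pass over all genes, nor did the chemokines Cxcl10 (-0.82, SE 0.21, adjusted p = 0.144) and Cxcl9 (-0.38, SE 0.27, adjusted p = 0.651). Tgtp1, Tgtp2 and Pdcd1lg2 were the 3 members with positive values. The receptor chain Ifngr2 stood at 38.0 ± 5.22 and 23.2 ± 0.90 CPM (-0.71, SE 0.16, adjusted p = 0.105) and Ifngr1 at 1674 ± 381 and 1450 ± 93.5 CPM (-0.21, SE 0.15, adjusted p = 0.660). The Gbp, Irg and Tgtp genes and Serpina3g belong to families of closely related copies, so how reads were shared among these is uncertain.

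Antigen presentation genes had medians closer to 0. The class I list, which holds the peptide transporter and immunoproteasome genes, had a median of -0.28 over 20 members, 15 of them negative (camera adjusted p = 0.00135, and adjusted p = 0.213 with an estimated correlation). No member passed over all genes and 3 did when adjusted over the list alone: H2-T23 (-0.53, SE 0.11), Tap1 (-0.47, SE 0.11) and Tap2 (-0.41, SE 0.12). The class II list was not called (median -0.23 over 9 members, camera adjusted p = 0.225, 0 members adjusted over the list alone). Within it the transactivator Ciita was at 23.7 ± 2.89 and 15.1 ± 3.14 CPM (-0.65, SE 0.21, adjusted p = 0.243), Cd74 at 242 ± 97.8 and 290 ± 120 CPM (0.26, SE 0.32) and H2-Ab1 at 214 ± 26.6 and 199 ± 48.1 CPM (-0.10, SE 0.18). The class II list passed the threshold without control replicate 3 (adjusted p = 0.0358) and without IGF-1 replicate 2 (adjusted p = 0.0471). Genes driven mainly by type I interferon, such as Oasl2 (-0.39, SE 0.16) and Irf7 (-0.36, SE 0.19), had a median of -0.07 and a mean of 0.01 over 23 members and were not called (camera adjusted p = 0.361), except without IGF-1 replicate 2 (adjusted p = 0.0471).

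The lists of IGF-1's own pathway were lower. The FOXO list and the receptor signalling list share Insr, Irs1, Irs2 and Rictor, so they are not separate results. Genes that FOXO factors activate, and that PI3K-AKT signalling lowers, had a median of -0.29, with 18 of 21 members negative (camera adjusted p = 9.58e-05, and adjusted p = 0.213 with an estimated correlation). Adjusted over the list alone 5 members were lower, including Klf6 (-0.53, SE 0.11), the insulin receptor substrate Irs2 (104 ± 22.8 to 58.0 ± 9.63 CPM, -0.85, SE 0.18, adjusted p = 0.0940 over all genes) and the pro-apoptotic Bcl2l11 (-0.48, SE 0.13). The IGF and insulin receptor signalling list had a median of -0.16 over 29 members (camera adjusted p = 0.00348, and adjusted p = 0.213 with an estimated correlation). The PI3K subunit Pik3cd fell from 246 ± 21.2 to 147 ± 6.09 CPM (-0.74, SE 0.12, adjusted p = 0.0350). In all, 6 members were lower and 2 higher when adjusted over the list alone. The lower ones included Socs2 (-0.74, SE 0.16), Grb10 (-0.83, SE 0.18), Igf1r and Insr, and the higher ones included Igfbp4. The IGF-1 receptor Igf1r was at 117 ± 15.0 and 76.3 ± 17.2 CPM (-0.61, SE 0.17, adjusted p = 0.183) and the insulin receptor Insr at 62.0 ± 17.0 and 37.8 ± 8.22 CPM (-0.71, SE 0.22, adjusted p = 0.211). Irs1 had 4 counts over the control libraries and 2 over those with IGF-1, too few to test. NF-kB targets had a median of -0.33, with 15 of 16 members negative (camera adjusted p = 0.000146, and adjusted p = 0.362 with an estimated correlation), and Nfkbia (-0.56, SE 0.13), Bcl3 (-0.75, SE 0.18) and Traf1 (-0.49, SE 0.13) were lower when adjusted over the list alone.

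Genes of sterol and fatty acid synthesis, the targets of SREBP, were higher with IGF-1. The list's camera adjusted p was 1.94e-15 with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.0626). Of 31 measured members 27 were positive, with a median of 0.50, or 41.4% higher. Idi1 (24.0 ± 3.56 to 54.8 ± 2.77 CPM, log2 fold change 1.19, SE 0.16, adjusted p = 0.0193) and Msmo1 (190 ± 4.95 to 292 ± 18.0 CPM, 0.62, SE 0.11, adjusted p = 0.0461) passed over all genes. Adjusted over the list alone, 16 were higher, among them Fdps (0.73, SE 0.15), Hmgcs1 and Sqle, and 1 was lower.

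The other 5 lists called higher had smaller medians, and 0 of their members passed over all genes. Chaperones and other targets of the unfolded protein response, such as Pdia3 (0.56, SE 0.16) and Manf (0.42, SE 0.12), were positive in 18 of 19 members (median 0.24, camera adjusted p = 0.000106, and adjusted p = 0.213 with an estimated correlation). Glycolysis genes, led by Pgk1 (0.55, SE 0.12) and Ero1a (0.60, SE 0.14), had a median of 0.16 over 26 members (camera adjusted p = 0.00135, and adjusted p = 0.362 with an estimated correlation), with 2 higher when adjusted over the list alone. Oxidative phosphorylation subunits had a median of 0.15 over 33 members (camera adjusted p = 0.00173, and adjusted p = 0.573 with an estimated correlation), and Atp5pb (0.32, SE 0.12) and Uqcrc2 (0.30, SE 0.13) had the smallest p. ATF4 and amino acid genes, such as Psph (0.70, SE 0.17) and Gars1 (0.33, SE 0.12), had a median of 0.16 over 32 members (camera adjusted p = 0.0138, and adjusted p = 0.213 with an estimated correlation). MYC and ribosome biogenesis genes, such as Ddx21 (0.35, SE 0.12) and Ppan (-0.39, SE 0.15), had a median of 0.16 over 32 members (camera adjusted p = 0.0430, and adjusted p = 0.275 with an estimated correlation). The calls of glycolysis without IGF-1 replicate 3 (adjusted p = 0.0612), oxidative phosphorylation without IGF-1 replicate 2 (adjusted p = 0.169) and ATF4 without control replicate 1 (adjusted p = 0.0738) were lost. The MYC call was lost without control replicate 1 (adjusted p = 0.189), control replicate 2 (adjusted p = 0.0583), IGF-1 replicate 2 (adjusted p = 0.0582) or IGF-1 replicate 3 (adjusted p = 0.101), and with 5 other settings (adjusted p from 0.0522 to 0.108).

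**Figure D2:**
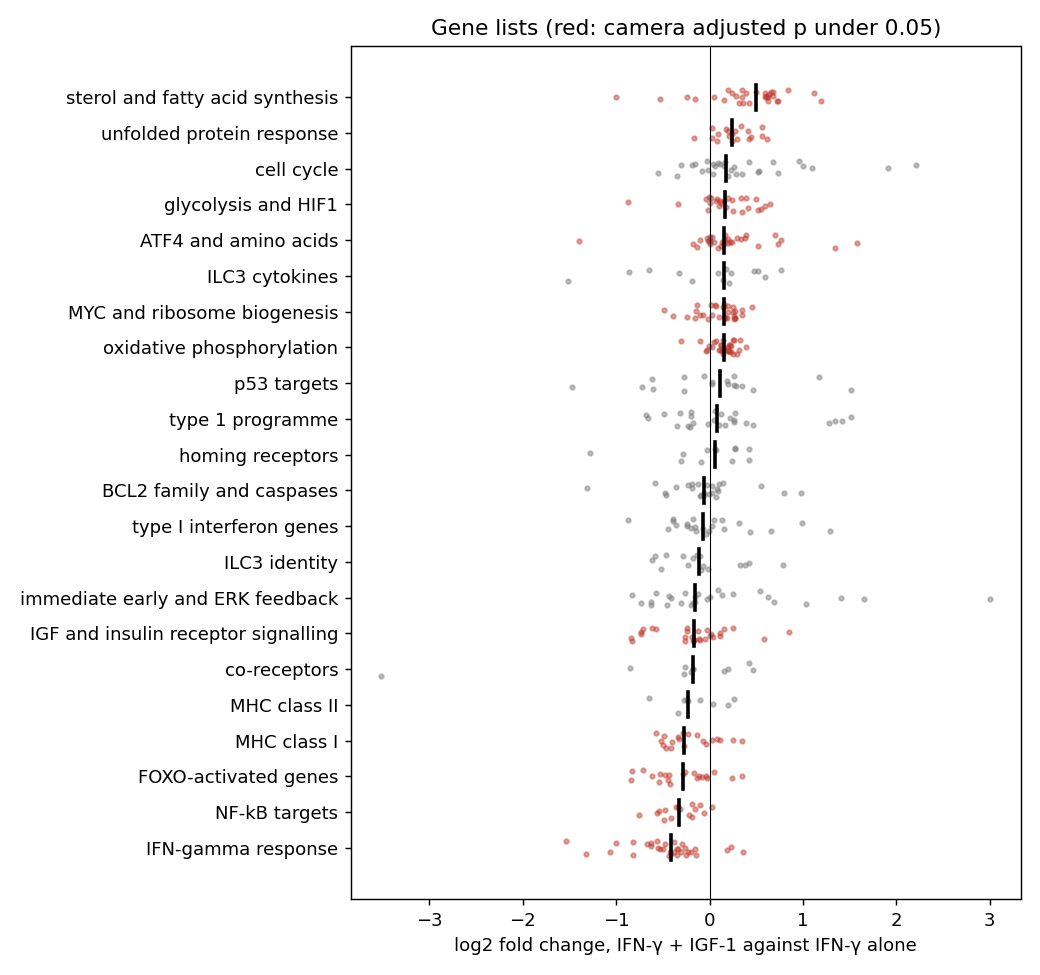
Log2 fold changes (IFN-γ plus IGF-1 over IFN-γ alone) of the measured members (points) of the 22 gene lists, with each list's median as a black line; lists in red had a camera adjusted p under 0.05 with the preset correlation. The IFN-γ response has the lowest median (-0.42) and sterol and fatty acid synthesis the highest (0.50).

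Among genes of ILC3 identity, Il2ra (1015 ± 119 and 659 ± 42.9 CPM, -0.62, SE 0.12, adjusted p = 0.0688) and Tcf7 (264 ± 16.9 and 184 ± 9.05 CPM, -0.52, SE 0.11, adjusted p = 0.0945) missed the threshold, as did Ahr (-0.47, SE 0.19, adjusted p = 0.360) and Il23r (-0.24, SE 0.14, adjusted p = 0.549). When adjusted over the list alone, 2 members, including Id2, were higher and Il2ra and Tcf7 lower, and the list was not called by camera (median -0.12 over 16 members, adjusted p = 0.225), while fry called it lower (adjusted p = 0.0289). The cytokine list was not called either (median 0.16 and mean -0.03 over 14 members, camera adjusted p = 0.333). Csf2 rose from 140 ± 13.2 to 237 ± 24.9 CPM (0.76, SE 0.13, adjusted p = 0.0392). Adjusted over the list alone, Hbegf (0.52, SE 0.13) was also higher and Lta (430 ± 57.9 to 275 ± 52.7 CPM, -0.65, SE 0.16) lower. Il22 stood at 267 ± 82.3 and 311 ± 37.4 CPM (0.22, SE 0.20, adjusted p = 0.738) and Il17f at 10.1 ± 6.65 and 15.1 ± 5.31 CPM (0.59, SE 0.42, adjusted p = 0.649). Il17a had 35 counts over the control libraries, all in control replicate 1, and 39 over the IGF-1 libraries, and its difference was not called (0.17, SE 1.55, adjusted p = 0.981). The cytokine list passed the threshold without control replicate 3 (adjusted p = 0.0337), and without IGF-1 replicate 3 its median was -0.08.

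The type 1 programme, genes of ILC1s and natural killer (NK) cells, held 2 higher genes, Ncr1 and Nkg7, and was not called (median 0.07 over 26 members, camera adjusted p = 0.0593). A further gene, the pore-forming Prf1 (1.42, SE 0.42), was higher when adjusted over the list alone, and Il18r1 (-0.68, SE 0.15) was lower. The factor Tbx21 was at 19.4 ± 6.41 and 23.2 ± 3.18 CPM (0.26, SE 0.24, adjusted p = 0.758), and Ifng at 0.85 ± 0.75 and 0.75 ± 0.50 CPM (adjusted p = 0.971). The list passed the threshold with no filter on low counts (adjusted p = 0.0175) and without control replicate 3 (adjusted p = 0.0332), IGF-1 replicate 1 (adjusted p = 0.0402) or IGF-1 replicate 3 (adjusted p = 0.0431), and its median was -0.05 without control replicate 2.

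Immediate early and ERK feedback genes went both ways: the median was -0.16, the mean 0.12 and camera's direction upward (adjusted p = 0.426). Dusp6 rose from 13.6 ± 2.40 to 36.0 ± 5.71 CPM, and adjusted over the list alone 3 members, including Spred1 (1.65, SE 0.37), were higher and Jun (-0.62, SE 0.13) lower; without control replicate 3 the list's adjusted p was 0.0380 and its median 0.06. The remaining lists were not called: BCL2 family and caspases (median -0.06, camera adjusted p = 0.50), cell cycle (0.18, adjusted p = 0.225), p53 targets (0.11, adjusted p = 0.991), homing receptors (median 0.06, mean -0.02, adjusted p = 0.496) and co-receptors (-0.18, adjusted p = 0.875). Cell cycle passed the threshold without IGF-1 replicate 2 (adjusted p = 0.0471). In these lists 0 members passed over all genes, and 2 did when adjusted over the list alone, the p53 targets Trp53inp1 (-0.73, SE 0.17) and Btg2 (-0.61, SE 0.15). Bcl2 stood at 751 ± 183 and 499 ± 74.7 CPM (-0.59, SE 0.18, adjusted p = 0.227), Ccnd3 at 108 ± 41.9 and 180 ± 28.3 CPM (0.73, SE 0.24, adjusted p = 0.243), the tissue-homing receptor Cxcr6 at 3024 ± 519 and 4040 ± 150 CPM (0.42, SE 0.12, adjusted p = 0.201) and Cd69 at 95.2 ± 11.8 and 131 ± 12.03 CPM (0.46, SE 0.13, adjusted p = 0.192).

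Markers of other cell types and of RNA quality did not separate the groups as lists. Of 12 marker lists 11 could be tested and 0 were called, with camera adjusted p of 0.280 for mitochondrially encoded mRNAs (median 0.16), 0.408 for NK cells (0.40) and for nuclear long noncoding RNAs (-0.41), 0.467 for heat shock genes (0.02) and 0.469 for epithelial markers (-0.27). The values were 0.617 for B and plasma cells (median 0.21, mean -1.23), myeloid cells (median 0.18, mean -0.21) and erythroid genes (-0.87), 0.656 for fibroblast and endothelial genes (-0.12), 0.882 for T cells (median -0.12, mean 0.03) and 0.992 for ILC2s (median 0.09, camera's direction downward), and no mast cell marker had enough counts to test. Of the 14 T cell markers 7 were tested, and Trac, Trbc1, Trdc and Tcrg-C1 had no row of counts under these names. Mitochondrially encoded mRNAs and nuclear long noncoding RNAs passed without control replicate 1 (adjusted p = 0.0163 and 0.00553), and mitochondrially encoded mRNAs and myeloid markers without IGF-1 replicate 3 (adjusted p = 0.0272 for both). With limma-voom and sample quality weights mitochondrially encoded mRNAs passed too (adjusted p = 0.00373). Their most abundant members were COX1 (4554 ± 765 and 5378 ± 389 CPM), Neat1 (1074 ± 315 and 745 ± 159 CPM) and Fcer1g (2347 ± 307 and 3172 ± 824 CPM). Epcam was the single marker that passed over all genes, falling from 38.6 ± 6.97 to 17.6 ± 3.28 CPM (-1.13, SE 0.20, adjusted p = 0.0442), while the other 4 epithelial markers tested were under 2 CPM in both groups. The plasma cell marker Sdc1 was at 47.6 ± 5.70 and 26.9 ± 2.44 CPM (-0.82, SE 0.16, adjusted p = 0.0598). The immunoglobulin gene Igha had 46944 counts in control replicate 3 and between 40 and 192 in each of the other libraries.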

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

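The robust dispersion fit and the length and GC offset were chosen after seeing the data. The decrease of the IFN-γ response list kept its direction and its side of the threshold in every alternative, with medians from -0.44 to -0.37. All 67 genes called, or the 63 of them still tested with the stricter filter, kept their direction and an unadjusted p under 0.05 in every refit. They were picked by small p-values on these same libraries, so this is not separate support. How many passed adjustment varied widely, and where no reason is given the cause was not tested. With the replicate block 3 genes were higher and 5 lower. Whether the replicate numbers pair the libraries is not known. Deviations from the group mean of log2 CPM correlated at -0.052, 0.0031 and 0.064 between control and IGF-1 libraries of replicates 1, 2 and 3. These low values do not settle whether the design was paired. DESeq2 gave 200 higher and 256 lower, with the block 151 and 217, limma-voom 36 and 60, and limma-voom with sample quality weights 124 and 159. With no filter 171 were higher and 258 lower, and with the stricter filter, which tests fewer genes, 63 and 115. In the fit with no filter the prior degrees of freedom were infinite, against 6.40 in the reported fit. Each gene's own spread then carried no weight in the test. Igha, high in control replicate 3 alone, passed there with an adjusted p of 2.92e-265. At an adjusted p of 0.1 the counts were 57 and 87, and at 0.01 they were 1 and 1, by construction of the threshold. Leaving out a library, which leaves 2 in its group, gave 0 to 24 higher and 0 to 31 lower. With the fewest, 0 by edgeR without IGF-1 replicate 1, 1233 genes had an unadjusted p under 0.05.

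With an estimated inter-gene correlation 0 lists were called higher and 1 lower. The call of MYC and ribosome biogenesis was lost with the replicate block (adjusted p = 0.0615), library size alone (adjusted p = 0.0679), DESeq2 and the block (adjusted p = 0.0522), limma-voom with quality weights (adjusted p = 0.108) and the stricter filter (adjusted p = 0.102). With the estimated correlation and 4 of the leave-outs it was lost in 10 of 20 alternatives, over which its adjusted p ranged from 0.00797 to 0.275. The type 1 programme was called in 4 of 20, with no filter (adjusted p = 0.0175) and in 3 leave-outs, over a range of 0.0175 to 0.315. Marker lists called numbered 1 with sample quality weights and 0 to 2 when a library was left out. Over the same leave-outs the median was -0.25 to -0.11 for MHC class II, -0.078 to 0.21 for ILC3 cytokines, -0.049 to 0.15 for the type 1 programme, -0.20 to 0.059 for immediate early genes and -0.012 to 0.14 for homing receptors. It was -0.37 to 0.43 for B and plasma cell markers, -1.39 to 0.069 for epithelial markers, -0.23 to 0.29 for fibroblast and endothelial markers, -6.33 to 1.55 for erythroid markers and -0.070 to 0.18 for heat shock genes. Single genes whose direction turned were Cd74 (-0.077 to 0.63), H2-Ab1 (-0.25 to 0.082), Hba-a1 (-6.33 to 1.56), Hba-a2 (-11.10 to 1.55), Ifng (-0.66 to 0.78), Igha (-7.24 to 0.45) and Il17a (-0.41 to 6.69), and none of these 7 passed the threshold in the reported comparison, but with no filter Hba-a1 (-0.86) and Igha (-6.65) did.

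Other reversals were of results not called in the reported comparison. Ifng was 0.13 with the block and 0.14 with DESeq2 and the block. ILC2 markers had medians of -0.030 with the block, -0.030 with DESeq2 and the block, -0.016 with limma-voom and -0.076 with quality weights, and heat shock genes -0.0089 with library size alone. With no filter the median was -1.35 for B and plasma cell markers and 0.23 for fibroblast and endothelial markers. With the stricter filter it was 0.14 for co-receptors and 0.18 for T cell markers. Among members of at least 10 CPM it was 0.15 for co-receptors, 0.19 for T cell markers and -0.26 for B and plasma cell markers. Il17a, Ifng and Irs1 had fewer than 100 counts per group, which limits precision. Ifng counts also differed between the control libraries (8, 22 and 60), so depth alone may not account for the low precision.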

Other observations

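The tests of tubulin genes, ERK feedback genes, gene families, NK or ILC1 cells and NCR-positive ILC3s were chosen after the result was seen. The genes named in this part were also chosen after their values were seen. Among genes outside the lists, 3 tubulin genes were higher with IGF-1: Tubb6 (86.8 ± 11.7 to 178 ± 27.8 CPM, log2 fold change 1.03, SE 0.15), Tuba8 (0.91, SE 0.16) and Tuba1c (0.69, SE 0.12). A hypothesis is that tubulin genes, which encode the subunits of microtubules, may have risen together. The 8 other tested alpha and beta tubulin genes had a median of 0.38 and a camera p of 0.00234 upward, and p = 0.110 with an estimated correlation. Tubb4b (0.52), Tubb5 (0.44) and Tuba1b (0.38) were positive and Tubb2a (-0.44) negative. Reads of such similar genes may be shared among them.

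Dusp6, a phosphatase induced by ERK, was higher, and its fellow ERK feedback genes Spred1 (1.65), Etv5 (3.00) and Spred2 (1.03) had positive values at low counts. The hypothesis that ERK feedback genes rose together was tested on 7 others and was not borne out for these. They had a median of -0.16 and a camera p of 0.683, and Spry2, among them, was at -0.73. Spred1, Etv5 and Spred2 were left out along with Dusp6, whereas the tubulin test left out only called genes. Leaving out genes already seen to be higher tilts the test against a rise, so it covers the 7 alone. Outside the lists the Fc receptor gene Fcgr3 was lower (255 ± 36.2 to 147 ± 10.4 CPM, -0.80, SE 0.14), as was the interferon-inducible Ifi209 (123 ± 13.9 to 65.0 ± 2.94 CPM, -0.92, SE 0.13). The complement receptor gene C5ar1 was higher (1.07 ± 0.40 to 7.71 ± 0.32 CPM, 2.85, SE 0.42). Gpr12 had 0 counts over the control libraries and 208 over those with IGF-1, 66.7-fold higher if a floor of 3 counts is set for the control group. Pga5 had 19 and 520. PCR reads are not independent molecules, so such a floor gives no lower bound on the fold change, and it does not cover the spread between libraries.

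The lower IFN-γ response was weighed against 3 technical explanations. With each library's trend over transcript length and GC content taken out, the median stayed at -0.42 (95% bootstrap interval -0.49 to -0.30). This argues against such a trend as the whole cause. The bootstrap, here and for the ranges in brackets below, resampled member genes and not libraries. Its intervals therefore do not measure the spread between libraries or cultures. Over 4 library scalings the highest median was -0.41. The 17 members outside the Gbp, Irg and Tgtp families had a median of -0.42 (-0.63 to -0.34), so reads shared within those families do not account for it. A biological effect of IGF-1 stays as a hypothesis that was found and tested on the same libraries, and a difference between cultures other than IGF-1 was not tested.

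Ncr1, Nkg7, Cd160 and Cd244a, receptor and granule genes shared with NK cells, were picked from the called genes because they were higher, so their mean log2 fold change of 1.40 is set by that choice. The lists fixed beforehand were not called (type 1 programme adjusted p = 0.0593, NK cell markers adjusted p = 0.408), and Klrk1 (0.21) and Klrc1 (0.39) were not called either. NK cells or ILC1s in the sort would raise, by about as much, the other genes that they express and ILC3s do not. The 15 NK and type 1 genes with a control level below that of Ncr1 had a median of 0.23 (0.05 to 0.47), although Prf1, 1 of these 15, was at 1.42. The 15 were chosen by control level alone, and include Klrg1, which the gate excludes, and Ifng, under 1 CPM. Their median argues against such cells as the whole cause only as far as ILC3s do not express these genes themselves. Of the 12 NK cell markers only 4 had enough counts to test, and Eomes had 0 counts in every library. With the length and GC trend taken out the mean of the 4 was 1.36. Trdv4, a T cell receptor variable segment in none of the lists, was also higher (41.2 ± 2.35 to 82.3 ± 11.6 CPM, 1.00, SE 0.14, adjusted p = 0.0222). T cells as a source of the 4 were not tested. A larger share of NCR-positive ILC3s and regulation by IGF-1 stay open: 7 genes of that subset had a median of 0.21 (-0.32 to 0.26), but 4 of them were above Ncr1 in the control libraries, where a change in a small subset would be hidden.

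Igha stood at 1308 CPM in control replicate 3 and at 1.20 to 5.54 CPM in the other 5 libraries. RNA of plasma cells in that library may be the source: Igkc, Jchain and Mzb1 together were 2486 times their highest sum elsewhere, in CPM without TMM scaling. Nearly all of that was Jchain, with 18629 counts there and 4 to 7 in each other library. Igkc had 4 counts there, while the segment Igkv19-93 had 14308 there and 0 elsewhere. Mzb1 had 59 and Tnfrsf17 64 counts there and 0 elsewhere, while Ighm, at 534 there, was not raised. The cells came from a lineage-negative gate, whose markers are not given in the sources used here. No explanation other than plasma cell RNA was tested.

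Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave as many genes (67, the highest other 3), 1 as many lists (11, the highest other 8) and 1 as large a median of the IFN-γ response (a size of 0.42, the highest other 0.17). Each of the other splits called lists too, from 1 to 8. Every such split still held more libraries of one real group on each side, so part of any real difference stayed in it. These calls therefore cannot show how often the preset correlation calls lists where nothing differs. For MHC class II 3 splits gave a median as large (0.23, the highest other 0.34), and for ILC3 cytokines 5 did (0.16, the highest other 0.31). The 10 splits are too few for a share under 0.05.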
